A study of Bos taurus with 10 samples.

How the data were processed

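RNA from skin biopsies of Brangus cattle (*Bos taurus*; a composite breed of Brahman and Angus ancestry), stored in RNAlater, was sequenced as paired-end libraries that do not keep the strand, on an Illumina NovaSeq instrument, per the labels' protocols. The series design text describes animals under heat stress and control animals. The titles name 5 libraries Ctrl and 5 libraries Strs, whereas the disease state entry puts the 5 Ctrl-titled libraries in the heat-stress case group and the 5 Strs-titled libraries in the control group. Both labels divide the 10 libraries into the same 2 sets, and they contradict each other on which set was heat-stressed. The sets are therefore called Ctrl-titled and Strs-titled, each fold change is Strs-titled over Ctrl-titled, and no expression value was used to choose between the labels. The labels give each library a number of its own but do not say in words that each came from a different animal, so the p-values measure the spread between these samples. No label gives a sequencing batch or date. The titles also carry a number after the letters PA, which is lower in every Ctrl-titled than in every Strs-titled library. What that number stands for was not settled here.

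The deposited table holds whole-number read counts, not normalized, for 7052 Ensembl gene identifiers in 10 columns, and each column name matches the title of 1 library. The submitters' processing notes name fastp 0.12.5, FastQC, STAR, featureCounts, DESeq2 1.26.0 and the genome build ARS-UCD1.2. The name of the deposited table describes it, in Spanish, as without zeros and without RP, and does not spell out RP. In its counts, 226 genes were at 0 in at least 1 library and 0 genes were at 0 in all 10. The annotation release, the counting settings and any further rule by which genes entered the table are not given in the sources used here. Genes left out of the table count neither in the table totals nor in the CPM values and shares computed from them. The table covers part of the bovine genes, so a column sum is called a table total and is not the sequencing depth of the library. Table totals were 490752 to 659756 counts in Ctrl-titled libraries and 2453542 to 8051190 in Strs-titled libraries. A single read was therefore worth 1.52 to 2.04 CPM, a gene's count scaled to the table total of its library, in the former and 0.124 to 0.408 CPM in the latter. Intervals and floors cover counting error only.

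The table identifies genes by Ensembl identifier alone. The gene table used here, of assembly ARS-UCD2.0, carried an Ensembl identifier in 0 of its rows, so 0 of the 7052 identifiers were paired with a symbol, coordinates, gene length or GC content. The 32 gene lists of heat shock, skin cell type, immune and metabolic genes that had been fixed before the data were examined were not tested for this reason, and the 7 genes that were to be reported in any case (HSPA1A, HSPA8, HSPH1, HSP90AA1, DNAJB1, HSF1 and PRLR) have no value here. Overlapping or antisense genes cannot be told apart in counts that do not keep the strand, and near-identical gene copies were not identified.

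The groups were compared with edgeR 4.0.16 (R 4.3.3). Genes were filtered with filterByExpr, which removed 5 and left 7047, and libraries were scaled with TMM factors. Two-sided quasi-likelihood F tests (robust glmQLFit) were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called a change. All 10 libraries entered the fit with no covariate, and the standard error of a log2 fold change was taken as its size divided by the square root of F. Log2 CPM values for principal components used a prior count of 2. Differences in component scores, table totals and top-gene shares were tested with two-sided exact permutation tests over the 252 divisions of 10 libraries into 5 and 5, whose smallest p is 0.00794. Single-library shares carry exact Clopper-Pearson 95% intervals. A fold against a group at 0 counts was computed as a bound against a floor of 3 counts over the whole group.

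The rule for named genes took those with the largest and smallest log2 fold change among called genes with a mean of at least 20 counts and with all libraries of 1 group beyond the mean of the other. It also asked for a gene symbol; that condition was dropped because there were none, after the data had been seen, and only 2 identifiers per direction are printed. Any other identifier is marked as chosen after its values were seen.

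The fit was tested on simulated data with the real library totals, gene abundances and dispersions. For this comparison, run on 7052 genes, it recovered 96% of 100 genes changed 4-fold and 32% of 100 genes changed 2-fold. It called 6 of 6852 unchanged genes. The simulation thus left most genes unchanged, whereas 4775 of 7047 tested genes were called in the data. These rates therefore do not show how the fit performs when most genes differ. No 2 libraries of a group were copies: the smallest chi-square per degree of freedom over the 20 within-group pairs was 4.00.

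Alternatives fixed before the data were examined were RLE and upper quartile factors, DESeq2 1.42.0, limma 3.58.1 voom with and without sample quality weights, no filter, a filter of 1 CPM in 5 libraries, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a test against a 1.5-fold change, and leaving out each library. Alternatives chosen after seeing the data were table totals with no scaling factors, thinning every library to 490752 counts (20 draws), leaving out genes above 1% of any library, and keeping genes with a mean of at least 200 counts.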

Results

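The transcriptome of skin biopsies was counted in 10 Brangus cattle libraries, 5 titled Ctrl and 5 titled Strs, to compare animals under heat stress with control animals. The titles and the disease state entries name the heat-stressed group the opposite way round, so every direction below is that of the titles, and the direction relative to heat stress is open. The table held 7052 genes. Table totals averaged 566000 counts ± 62090 (SD, n = 5) in Ctrl-titled libraries and 6362812 counts ± 2240382 (SD, n = 5) in Strs-titled libraries, an 11.2-fold difference of the means, with no overlap (two-sided exact permutation p = 0.00794, the smallest this design allows). The median gene had 25 to 36 counts in a Ctrl-titled library and 129 to 411 in a Strs-titled library. Between 42 and 79 genes were at 0 counts in a Ctrl-titled library, and between 2 and 22 in a Strs-titled library. Every gene in the table had at least 135 counts summed over the 5 Strs-titled libraries, whereas the sum over the 5 Ctrl-titled libraries went down to 0.

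**Figure D1:**
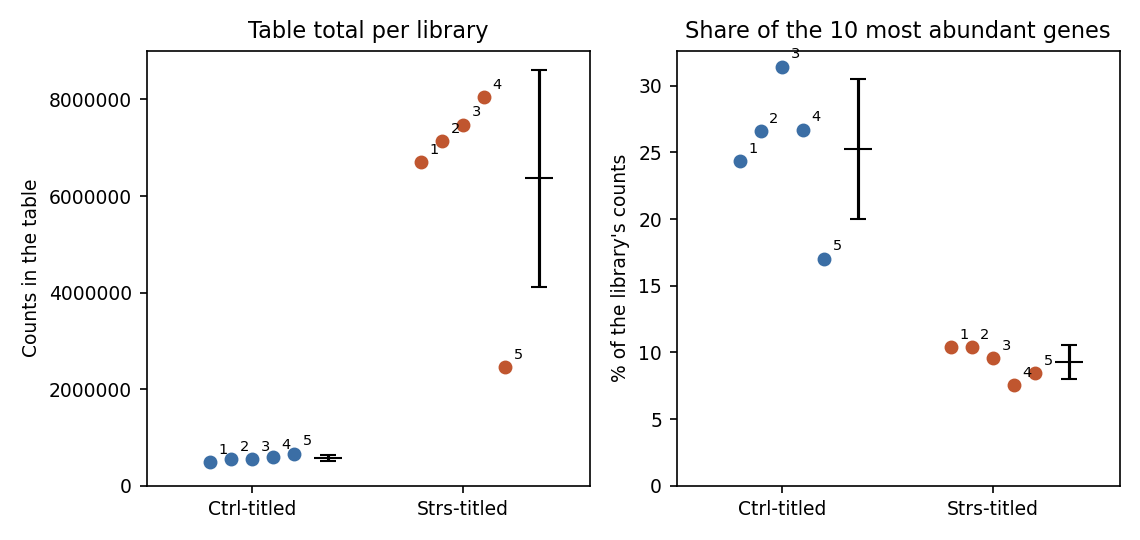
Left, counts in the deposited table per library; right, percent of each library's counts in its 10 most abundant genes. Points are libraries numbered by replicate, and the black bar is the mean ± SD of 5; Ctrl-titled totals lie between 490752 and 659756 counts and Strs-titled totals between 2453542 and 8051190.

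The first question was how far the skin profiles of the groups resembled each other. Gene ranks agreed closely within each group and weakly between them. Spearman's rho across the 7052 genes averaged 0.883 (range 0.860 to 0.914) over the 10 Ctrl-titled pairs and 0.894 (0.855 to 0.934) over the 10 Strs-titled pairs. Over the 25 pairs that joined the groups it averaged 0.282 (0.212 to 0.337). Genes are not independent replicates, so these values describe the libraries. Pearson's r of log2 CPM averaged 0.866, 0.894 and 0.328 in the same order. All 10 libraries correlated more strongly with their own group than with the other. The first principal component held 75.6% of the variance and separated the groups, with mean scores of -76.7 ± 4.14 (SD, n = 5) and 76.7 ± 14.5 (SD, n = 5; two-sided exact permutation p = 0.00794, 0.0317 after Benjamini-Hochberg adjustment over the first 4 components). Components 2 to 4 held 4.82%, 4.05% and 3.61%; their scores are uncorrelated with the first by construction, so the tests of their group difference, counted in that adjustment, carry no information.

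**Figure D2:**
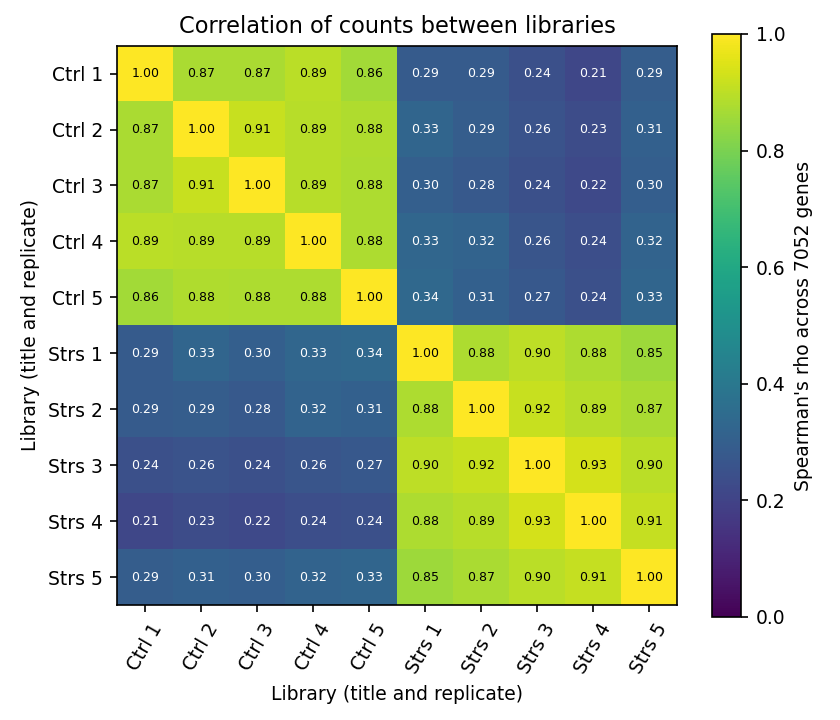
Spearman's rho of counts across 7052 genes for every pair of libraries; axes list the libraries by title and replicate, and colour runs from 0 to 1. The blocks of same-titled libraries lie between 0.855 and 0.934 off the diagonal, and those that join the groups between 0.212 and 0.337.

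The most abundant genes also differed. The 10 most abundant genes of a library took 25.2% ± 5.26 (SD, n = 5) of its counts in Ctrl-titled and 9.26% ± 1.25 (SD, n = 5) in Strs-titled libraries (two-sided exact permutation p = 0.00794). The 10 most abundant genes by group mean had 1 gene in common. Of the 100 most abundant genes of each group, 40 were shared, against 1.42 for independent lists, and of the 1000 most abundant, 469 were shared, against 142. Over pairs of libraries, the 100 most abundant genes had on average 82.7 in common within the Ctrl-titled group, 87.2 within the Strs-titled group and 35.6 between groups.

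The main comparison asked which genes differed between the groups. Of 7047 genes tested, 4775 (67.8%) changed, 2506 higher and 2269 lower in Strs-titled libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median change was 2.82-fold among genes that rose and 3.17-fold among genes that fell, and the median log2 fold change was 0.11 over all tested genes. A change of at least 2-fold was estimated for 3671 of the called genes, of at least 4-fold for 1685 and of at least 8-fold for 710. Genes that rose made up 52.5% of all called genes, 43.9% of those changed at least 4-fold and 34.6% of those changed at least 8-fold. The balance of directions among all called genes depended on the fit: genes that rose made up 49.7% of the calls with limma voom and 57.9% with upper quartile factors. Scaling factors set the zero point of every fold change. With most genes called, the number of calls, their balance and the median log2 fold change rest on that zero point. For 3757 genes (53.3%) the log2 CPM of the 5 libraries of each group did not overlap, against 0.794% by chance. The genes that rose took 18.1% ± 2.42 (SD, n = 5) of the counts of Ctrl-titled libraries and 65.3% ± 1.74 (SD, n = 5) of those of Strs-titled libraries. The genes that fell took 61.4% ± 2.65 (SD, n = 5) and 12.1% ± 1.10 (SD, n = 5), and the 2272 genes not called took 20.5% ± 0.860 (SD, n = 5) and 22.6% ± 1.06 (SD, n = 5). These shares are of genes chosen by the same test and are not independent evidence of the change.

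Changed genes were found across the range of abundance. In order of rising mean log2 CPM, 66.1%, 62.9%, 69.1% and 72.9% of the genes in each of 4 bins of equal size changed. Genes that rose made up 59.7%, 48.5%, 49.0% and 52.8% of those calls. The smallest sum of a gene over the 10 libraries was 273 counts, and Strs-titled libraries held most of the counts. If genes entered the table by their summed counts, a gene low in Strs-titled libraries would be missed more readily than one low in Ctrl-titled libraries. A rule against zeros in single libraries would act the other way, since Ctrl-titled libraries held more zeros. The rule is not given, so the direction of any such loss is open. The shares of directions, here and over all called genes, therefore describe the genes in the table only.

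Among the genes that rose, ENSBTAG00000026886 had 264 to 1280 counts in Strs-titled libraries (141 CPM ± 23.1, SD, n = 5) and 0 counts in all 5 Ctrl-titled libraries. Against a floor of 3 counts over the whole Ctrl-titled group (1.06 CPM) it was at least 133-fold higher (edgeR adjusted p = 6.4e-08). The ratio of its pooled counts per table total had a 95% counting interval that began at 112, a lower bound than the floor gives. ENSBTAG00000009713 had 160 to 705 counts in Strs-titled libraries (82.6 CPM ± 10.8, SD, n = 5) and 1 count in the Ctrl-titled group, in replicate 5, without which that group was at 0 counts. The ratio of the pooled counts per table total was 242 (95% counting interval 43.4 to 9553; edgeR adjusted p = 3.0e-08). Among the genes that fell, ENSBTAG00000053749 averaged 785 CPM ± 238 (SD, n = 5) in Ctrl-titled and 14.0 CPM ± 6.04 (SD, n = 5) in Strs-titled libraries. Its log2 fold change was -5.95 (SE 0.34, edgeR adjusted p = 1.3e-08). ENSBTAG00000051730 was the most abundant gene of each Ctrl-titled library, at 4.56% to 18.7% of the counts (mean 120658 CPM ± 50477, SD, n = 5), and averaged 561 CPM ± 1100 (SD, n = 5) in Strs-titled libraries. Its log2 fold change was -7.91 (SE 1.55, edgeR adjusted p = 0.0013). Strs-titled replicate 5 held it at 0.253% of its counts (95% exact interval 0.247 to 0.259), against 0.00631% to 0.00780% in the other 4 libraries of that group. Without that library the log2 fold change was -10.88 (edgeR adjusted p = 3.4e-08). Over the 20 edgeR alternatives that tested this gene the adjusted p was 3.4e-08 to 0.0037, and over the 3 DESeq2 and limma alternatives it was 2.3e-12 to 1.5e-06. What these identifiers encode was not analysed here.

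**Figure D3:**
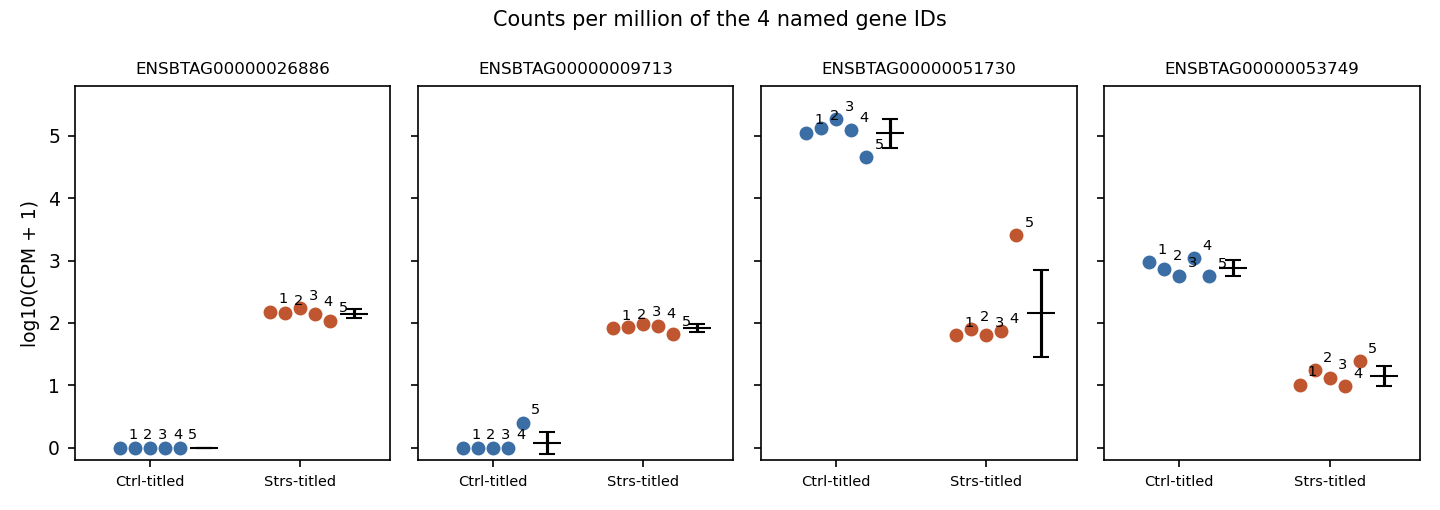
CPM of the 4 named gene identifiers in each library, on a log10(CPM + 1) scale; points are libraries numbered by replicate, and the black bar is the mean ± SD of the 5 plotted values. Each gene's groups do not overlap, and Strs-titled replicate 5 stands above the other 4 of its group for ENSBTAG00000051730.

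The group of each library coincided with its table total and with the order of the PA numbers in the titles. The labels give no batch within which the comparison could be repeated. Effects of group, of library preparation and of read processing on these counts cannot be told apart in this design.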

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

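The results below are values of a single library that stood far from the other 4 of its group by a gap test. For continuous values, chance alone passes that test in about 1 in 20 groups. A library stood apart in this way in 6 of the 20 groups of values checked. The rate does not hold for counts of single reads, and some of the 6 values share a gene. That rate therefore cannot say whether 6 is more than chance gives.

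Strs-titled replicate 5 had a table total of 2453542 counts, against 6701794 in the next lowest library of its group. The same library held 0.964% of its counts (95% exact interval 0.952 to 0.977) in the 4 genes that fell in Strs-titled libraries and averaged over 1% of Ctrl-titled counts, against at most 0.0640% in the other Strs-titled libraries and 11.4% to 27.7% in Ctrl-titled libraries. ENSBTAG00000051730, which is 1 of those 4 genes, stood at 2530 CPM in it, against at most 78.0 CPM in the others of its group.

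Strs-titled replicate 4 had 22 genes at 0 counts, against 6 in the next library, although its table total was the highest of the 10. Strs-titled replicate 1 had a second principal component score of -11.8, against 1.3 for the next library of its group. Ctrl-titled scores on that component spread more widely, from -30.0 to 48.1. Ctrl-titled replicate 5 had 1.52 CPM of ENSBTAG00000009713, which is 1 read, against 0 in the other 4 libraries of its group.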

How the results depend on the processing

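The 4775 calls (2506 higher, 2269 lower) stayed within 1.5 times under every alternative run except 1. Under scaling, tool, filter and surrogate-variable alternatives the count was 4265 (limma voom) to 4916 (DESeq2), and it was 3676 against a 1.5-fold change. No gene called in both the standard fit and any of these alternatives changed direction, and between 93.7% (upper quartile factors) and 100% (1.5-fold test) of an alternative's calls were shared with it, or 83.0% with a minimum mean of 200 counts. Fits with no scaling factors, with thinned counts, without genes above 1% of any library and with a minimum mean of 200 counts, and the 1.5-fold test of the named genes, were tests chosen after seeing the data. The minimum of 200 counts left 3209 genes and 2175 calls, 1151 higher and 1024 lower, with scaling factors computed anew. With table totals 11.2 times larger in the Strs-titled group, that minimum selects genes abundant in Strs-titled libraries, and the factors recentre the selected genes. It therefore tests neither the number nor the balance of the calls. Without 1 library the count was 4510 to 4708 (2362 to 2505 higher, 2100 to 2234 lower), and the first component held 74.7% to 77.0% of the variance. The counts gave no sign that the replicate numbers pair the libraries, which does not exclude a pairing. Same-numbered libraries correlated at -0.081 to 0.026 in their deviations from the group means, and 1 of 5 Ctrl-titled libraries correlated best with its own number. With the replicate block 4568 genes were called. Upper quartile factors moved the median log2 fold change of all genes from 0.11 to 0.27 and the share of calls that rose from 52.5% to 57.9%. That share was 49.7% with limma voom and 49.7% to 51.4% over the 20 thinned draws, 4 of which called more genes lower than higher. The 4 named genes kept their direction and stayed past the threshold in every alternative that tested them, with adjusted p up to 0.0037. The estimate for ENSBTAG00000051730 ran from -10.88 to -7.61. Table totals with 1 read worth up to 2.04 CPM limit what can be measured in Ctrl-titled libraries. Not run, for want of gene symbols, were the gene list tests and the fits with hair follicle or skeletal muscle lists as covariates.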

Other observations

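The thinning, the comparison without the most abundant genes, the ratio of table totals and the counts within 1 group were tests chosen after the data were seen. Libraries of the same title also differed in single genes. In the Strs-titled group, 37 genes had at most 3 counts in at least 1 library and at least 100 in another; in the Ctrl-titled group, with its lower totals, there were 3. ENSBTAG00000045737, the gene of these with the highest CPM in any Strs-titled library, was chosen after its values were seen. It had 26158, 104196 and 62948 counts in Strs-titled replicates 1, 2 and 4, 1 count in replicate 3 and 0 in replicate 5, and 47 to 375 counts in the Ctrl-titled libraries. It did not pass the group test (edgeR adjusted p = 0.0975).

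With every library thinned to 490752 counts, the biological coefficient of variation between libraries of 1 group was 0.281 in the Ctrl-titled and 0.317 in the Strs-titled group. The SD of log2 CPM across genes was 1.51 to 1.59 in Ctrl-titled and 1.46 to 1.68 in Strs-titled libraries at that total.

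The pattern most in need of a second look is the size of the group difference, 4775 of 7047 genes with a mean between-group rho of 0.282 in 1 tissue. Of 100 splits of the 10 libraries, drawn from 126 and the real one included, 1 called as many genes, and the highest of the others called 1. Every other split put libraries of both titles on each side, so the group difference itself raised the spread there and kept the calls low. The splits therefore show only that the real division ranked first of the 100. They do not measure how far chance is exceeded and do not exclude it. Unequal table totals as such are argued against, for the genes in the table only. After thinning to 490752 counts, between 88.0% and 89.4% of the calls were kept in the same direction in each of 20 draws. The thinned between-group rho averaged 0.278. The fit scales table totals either way and Ctrl-titled libraries were thinned little, so a large loss of calls was unlikely. Thinning drops reads at random, so it does not test what made the Ctrl-titled totals low or how genes entered the table. Without the 15 genes above 1% of any library, 98.4% of the 4763 remaining calls were kept, so those calls did not rest on the dominant genes. Both fits used scaling factors and the remaining genes kept their counts, so a large loss was unlikely from the start. This comparison is therefore weak evidence against an effect of a few dominant genes. A difference in library preparation, sequencing or read processing that coincides with the group may account for part or all of the pattern. It cannot be told apart from heat stress, because no label gives a batch within a group. The lowest Strs-titled total was 3.72 times the highest Ctrl-titled total. That ratio restates the gap in totals that raised the question, so it does not decide it. Heat stress itself stays open and untested.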
